A study of Mus musculus with 11 samples.

How the data were processed

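Liver total RNA of 11 female C57Bl/6 mice was hybridised to Illumina mouse BeadChips, 1 array per animal. The deposited non-normalised table holds, per the file headers, a mean bead signal for each of 45281 probes, an intensity on a linear scale that the authors exported from GenomeStudio (version not stated). The authors also deposited a detection p-value (p_value) per probe and array. The deposited normalised table holds intensity values on a linear scale that, judged from the values, the authors had background-subtracted and quantile-normalised between arrays. It was used only as an alternative.

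Groups were taken from the labels: vehicle control (3 arrays), 5'-AMP killed at 6 h (4; AIHM in the labels) and 5'-AMP killed at 12 h (4; RF or Rev Flip). What RF or Rev Flip stands for is not stated. The signals were background-corrected with normexp, with the background estimated from the detection p-values, given an offset of 16, quantile-normalised and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Probes with a detection p under 0.05 on at least 3 arrays were kept (16978 probes). Each of the 12512 gene symbols was represented by its probe with the highest mean over all arrays, and 3260 genes had more than 1 kept probe. Of the symbols 6779 matched a current symbol, 3809 a synonym and 1924 none.

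All 11 arrays entered 1 limma fit of group means (8 residual degrees of freedom, 4.18 prior), with 3 contrasts: 6 h against control, 12 h against control and 12 h against 6 h. Two-sided moderated p-values were adjusted by Benjamini and Hochberg over all genes within a contrast, with a threshold of 0.05. Within each contrast 41 lists fixed from textbook knowledge (28 gene lists and 13 cell type marker lists) were tested with camera of limma at a preset correlation of 0.01, adjusted over the 41. Members were also counted adjusted over the list alone. Camera with an estimated correlation and fry, whose directional p tests whether the genes of a list move on balance one way without comparing them with other genes, were alternatives. The design, the lists, the gene naming rule and all alternatives but 3 were chosen before the data were examined.

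Genes were named by this rule. For each comparison with control, the 8 largest changes in each direction were taken, and for 12 h against 6 h the 5 largest. They had to pass the threshold, have arrays that did not overlap between the groups, have a probe detected on every array of the higher group, and bear more than a clone or predicted name. For each list and each comparison with control, up to 3 called members with the largest change were taken, or the member with the smallest p where none passed and the list is mentioned. Clps, Pnlip, Cirbp, Rbm3, Per1, Per2, Arntl, Dbp, Nr1d1, Pck1, Ppargc1a, G6pc, Cyp7a1, Fgf21, Pdk4, Adk, Nt5e and Ada were always taken. Of the list members, those of some lists are left out as whole parts.

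Where a probe was undetected on every array of a group, a fold is given as a lower bound: the mean of the brighter group against, in the dimmer group, the higher of each array's own value and its lowest detected signal. In list medians taken with bounds, genes below background in both groups, or whose bound did not keep the sign, were left out. Such medians can thus rest on fewer genes and can rise. Overlap of both times was compared with independent lists and with 100 simulated sets of unchanged groups against shared controls. Array signals ran from 412 to 635 on average, and the number of arrays limits the precision.

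The method was tested on simulated data with 200 changed genes among 12512. Of 100 changes of 1 log2 unit it recovered 87 at 6 h, 86 at 12 h and 92 between the times, and of 100 changes of 2 log2 units 100, 100 and 99, with 7, 12 and 8 false calls. The simulated noise was normal, independent between genes and free of chip differences. These figures therefore do not cover chip differences, outlying arrays or genes that vary together.

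The alternatives were no background correction, median centring, the authors' normalised values, no filter or a stricter one (detection p under 0.01 on all 11 arrays), all probes or the mean of a gene's probes, only the compared groups, array weights, a trended and robust variance, the replicate number as a block, the chip as a block, and leaving out each array. Chip as a random block, array brightness as a covariate and lists without members shared with the immediate early genes were chosen after seeing the data. All deposited columns of values were used.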

Results

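Gene expression was measured in liver total RNA of female C57Bl/6 mice on Illumina mouse BeadChips, 1 array per animal. The labels give 3 groups. They are vehicle controls (3 arrays), animals killed 6 h after 0.5 mg/g body weight of 5'-adenosine monophosphate (5'-AMP; 4 arrays) and animals killed 12 h after that dose (4 arrays). The series calls the 6 h group AIHM and the 12 h group RF, and the titles of the 12 h samples read Rev Flip. What RF or Rev Flip stands for is not stated, so the 12 h group may differ from the 6 h group in more than time. The series title describes the state after the injection as hypometabolism, and the labels do not say when the controls were killed. Each array held 45281 probes. Between 15174 and 15663 probes were detected on the control arrays, 15403 to 15903 at 6 h and 15131 to 15589 at 12 h. The mean signal per array ran from 422 to 542 in the controls, 458 to 635 at 6 h and 412 to 494 at 12 h, in the file's intensity units. The number of arrays limits the precision. Values below are log2 fold changes from the limma fit with their standard errors, with 3 control arrays and 4 arrays at each time.

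On the first principal component, which held 32.7% of the variance, the 3 controls lay between -26.6 and -25.0. The 12 h arrays lay between 10.3 and 18.1, and the 6 h arrays were spread from -17.4 to 24.5.

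**Figure D1:**
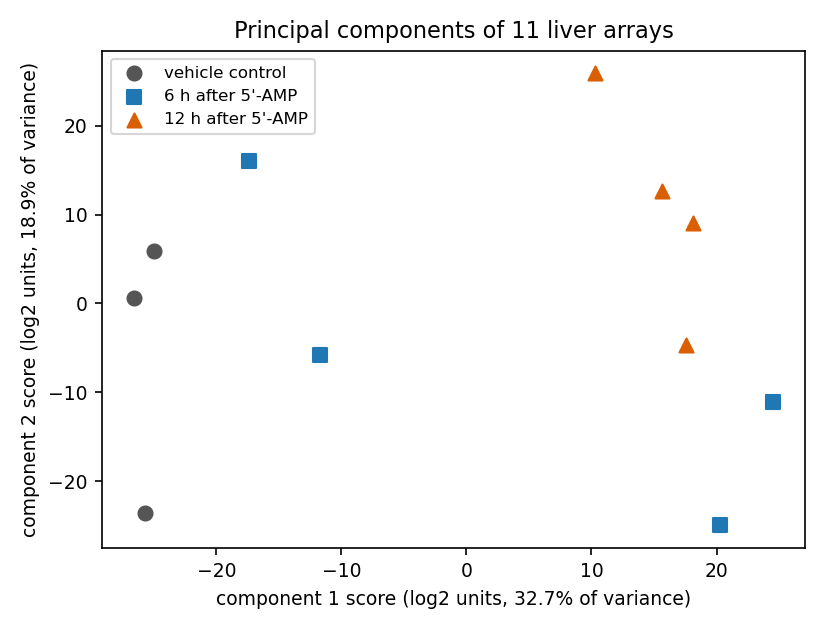
Scores of the 11 liver arrays on the first and second principal components of the normalised log2 values (log2 units, each point 1 animal, colour and shape by group). On the horizontal axis the controls sit between -26.6 and -25.0 and the 12 h arrays between 10.3 and 18.1, with the 6 h arrays spread from -17.4 to 24.5.

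The first comparison asks how liver transcripts differed from control 6 h after 5'-AMP. Immediate early genes, which encode transcription factors and regulators induced within minutes of a stimulus, rose most. The transcription factor gene Fos was higher by 6.73 ± 0.22 (adjusted p = 4.8e-09), detected on 1 of 3 control arrays and on all 4 arrays at 6 h. Atf3, a stress-induced transcription factor, was at least 15-fold higher, being below background on every control array (adjusted p = 2.5e-09). Egr1, a further early transcription factor, rose by 4.11 ± 0.44 (adjusted p = 0.000432). Of the 12512 genes tested, 141 passed the threshold, 91 higher and 50 lower, with 62 at least 2-fold higher and 16 at least 2-fold lower.

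The remaining genes among the 8 largest increases at 6 h were Fosb, Junb, Zfp36, Gdf15 and Dusp1. Fosb was at least 9.54-fold higher by the probe used (adjusted p = 5.2e-07), while its other probe, detected on every array, gave -0.13 (adjusted p = 0.916). The adjusted p of Fosb ran from 2.6e-09 to 0.894 over all alternatives, the highest with a stricter filter that left only the other probe. Junb rose by 3.48 ± 0.26 and Zfp36, which destabilises cytokine mRNAs, by 3.31 ± 0.25. Gdf15, a secreted stress cytokine, rose by 3.30 ± 0.29 and the MAP kinase phosphatase gene Dusp1 by 3.27 ± 0.22. The adjusted p of these 4 genes lay between 4.7e-06 and 6.0e-05.

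**Figure D2:**
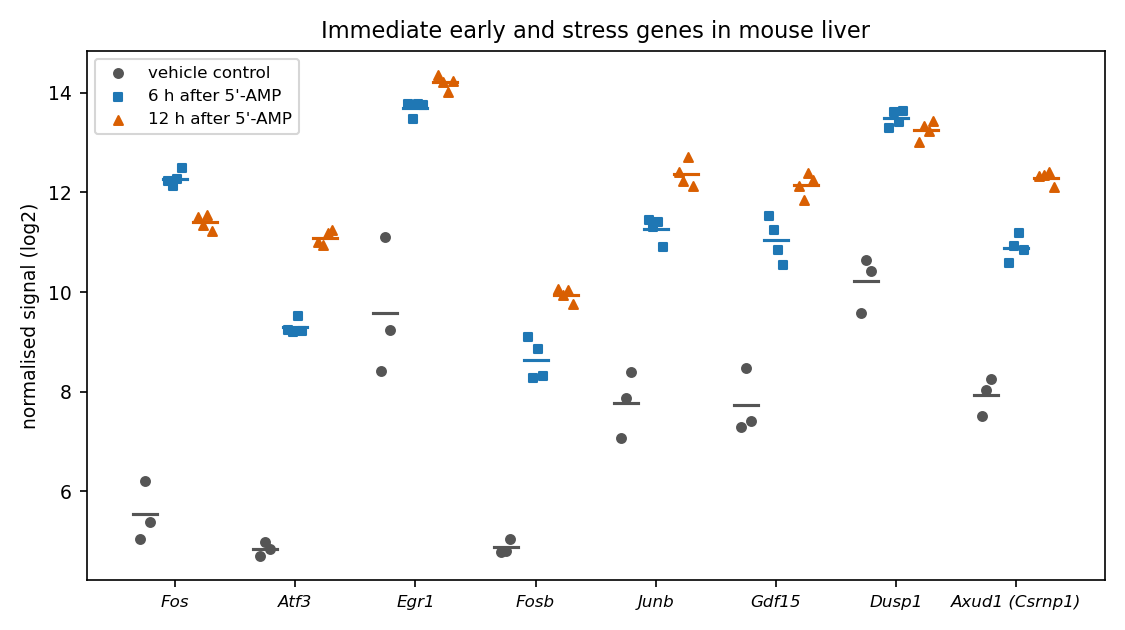
Normalised log2 signal of 8 immediate early and stress genes on each array (points, 1 animal each; lines, group means; 3 controls, 4 arrays at 6 h and 4 at 12 h). All 8 lie higher on every array after 5'-AMP than on every control, and Fos differed from control by 6.73 at 6 h and 5.86 at 12 h.

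Decreases at 6 h were smaller. Oraov1 (now LTO1) changed by -1.52 ± 0.31 (adjusted p = 0.0394, up to 0.149 without any single control, 6 h array 2 or 3 or 12 h array 3 or 4, and 0.00443 to 0.149 over all alternatives). Habp4, an RNA- and hyaluronan-binding protein gene, changed by -1.31 ± 0.23 (adjusted p = 0.0181, up to 0.102 without control 2 or 3 or 6 h array 3, and 0.00365 to 0.107 over all alternatives), and its other probe gave -0.38 (adjusted p = 0.405). The antisense transcript Tssc8 (now Kcnq1ot1) changed by -1.06 ± 0.23 (adjusted p = 0.0486, up to 0.192 without any single control, 6 h array 1, 2 or 4 or any single 12 h array, and 0.00148 to 0.192 over all alternatives), and Zfp385 (now Zfp385a) by -1.06 ± 0.20 (adjusted p = 0.0303, up to 0.104 without control 2 or 3, 6 h array 1 or 3 or 12 h array 1, 2 or 4, and 0.0150 to 0.152 over all alternatives). Dido1 changed by -1.02 ± 0.13 (adjusted p = 0.00203, up to 0.895 without any single control, and 0.00113 to 0.895 over all alternatives), and its other probes gave 0.07 and 0.25. A fit without control 1, 2 or 3 took one of those probes for Dido1 and gave 0.23, 0.17 and 0.35. Snx11, a sorting nexin gene, changed by -0.98 ± 0.18 (adjusted p = 0.0226, up to 0.122 without control 1 or 3 or 6 h array 1 or 3, and 0.00765 to 0.122 over all alternatives). Map3k7ip1 (now Tab1), an activator of a MAP kinase kinase kinase, changed by -0.88 ± 0.15 (adjusted p = 0.0137, up to 0.0795 without control 2 or 3, and 0.00535 to 0.0813 over all alternatives), with -0.84 (adjusted p = 0.0552) by its other probe. Zbtb7 (now Zbtb7a), a transcriptional repressor gene, changed by -0.87 ± 0.19 (adjusted p = 0.0465, up to 0.175 without any 1 of the 11 arrays, and 0.0228 to 0.175 over all alternatives).

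Among the gene lists fixed before the data were examined, 9 of 41 passed the camera test at 6 h, 8 upward and 1 downward. Of the 20 measured immediate early genes 13 rose and none fell, or 18 adjusted over the list alone (median 2.33, camera adjusted p = 1.0e-36). The immediate early genes gave adjusted p = 0.000305 with an estimated correlation, and 6.3e-41 to 0.000305 over all alternatives (medians of 1.42 to 2.50). With genes below background at their bounds, and those without a bound left out, the median was 2.41. Of 12 glucocorticoid targets 3 rose, or 6 adjusted over the list alone (median 0.72, camera adjusted p = 2.0e-06). The glucocorticoid targets gave adjusted p = 0.0553 with an estimated correlation, and 2.3e-08 to 0.0553 over all alternatives (medians of 0.58 to 0.90). The called targets were Dusp1, Per1 at 2.44 ± 0.24 (adjusted p = 0.000148) and the kinase gene Sgk (now Sgk1) at 1.49 ± 0.17 (adjusted p = 0.000693). Of 15 circadian clock genes 3 rose, with 7 higher and 2 lower adjusted over the list alone (median 0.29, camera adjusted p = 0.000635). The clock genes gave adjusted p = 0.240 with an estimated correlation, and 1.5e-06 to 0.240 over all alternatives (medians of 0.20 to 0.56). Clock genes had a median of 0.46 without control 2. The called clock genes were the repressor Per1, Bhlhb2 (now Bhlhe40) at 1.64 ± 0.21 (adjusted p = 0.00142) and Gm129 (now Ciart), a repressor of the clock. Gm129 was at least 2.04-fold higher, with both its probes below background on every control array and a fitted 1.48 ± 0.29 (adjusted p = 0.0323, up to 0.115 without any single control, 6 h array 1 or 12 h array 1, 2 or 4, and 0.00142 to 0.144 over all alternatives).

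Of 15 integrated stress response genes 3 rose (Atf3, Gdf15 and Cebpb), with 6 higher and 1 lower adjusted over the list alone (median 0.09, camera adjusted p = 0.00494). The stress response genes gave adjusted p = 0.126 with an estimated correlation, and 9.0e-05 to 0.126 over all alternatives (medians of -0.00 to 0.38). Stress response genes had a median of 0.03 without 6 h array 1, 0.04 without 6 h array 2, 0.38 without 6 h array 3, -0.00 without control 1, 0.22 without control 2 and 0.15 without control 3. Cebpb, a transcription factor gene, rose by 0.79 ± 0.15 (adjusted p = 0.0237, up to 0.121 without control 1 or 2 or 6 h array 1 or 3, and 0.00380 to 0.141 over all alternatives). Of 15 p53 targets 2 rose, or 5 adjusted over the list alone (median 0.19, camera adjusted p = 0.0159). The median with genes below background at their bounds, and those without a bound left out, was 0.23. The p53 targets gave adjusted p = 0.126 with an estimated correlation, and 0.000432 to 0.126 over all alternatives (medians of 0.16 to 0.34). The growth arrest gene Gadd45a rose by 1.86 ± 0.23 (adjusted p = 0.00129) and Trp53inp1 by 1.91 ± 0.35 (adjusted p = 0.0226, up to 0.118 without any single control or 6 h array 1, and 0.000142 to 0.126 over all alternatives), with 1.21 (adjusted p = 0.212) by its other probe. Of 11 inflammatory genes 2 rose, or 4 adjusted over the list alone (median 0.19, camera adjusted p = 0.0244). The inflammatory genes gave adjusted p = 0.517 with an estimated correlation, and 0.00448 to 0.517 over all alternatives (medians of 0.11 to 0.30), with a rise to as much as 0.111 without control 1 or 6 h array 4. Inflammatory genes had a median of 0.30 without 6 h array 3 and 0.12 without 6 h array 4. The neutrophil chemokine gene Cxcl1 rose by 2.26 ± 0.33 (adjusted p = 0.00424) and the interferon-induced chemokine gene Cxcl10 by 0.88 ± 0.14 (adjusted p = 0.0108, up to 0.0624 without control 1 or 2, and 0.00227 to 0.0756 over all alternatives). Of 15 gluconeogenesis genes 1 rose, or 4 adjusted over the list alone (median 0.09, camera adjusted p = 0.0499). The gluconeogenesis genes gave adjusted p = 0.430 with an estimated correlation, and 0.0175 to 0.430 over all alternatives (medians of 0.01 to 0.24), with a rise to as much as 0.137 without control 1, 6 h array 3 or 12 h array 1 or 2. Gluconeogenesis genes had a median of 0.15 without 6 h array 3 and 0.14 without 6 h array 4. The called gene was Snf1lk (now Sik1), a kinase that restrains CREB coactivators, at 2.33 ± 0.28 (adjusted p = 0.000986).

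Lists that passed with no single member called at 6 h were the erythroid markers and oxidative phosphorylation. All 7 measured erythroid genes, which include globin and haem genes carried by blood, had positive values, 0 called over all genes and 3 adjusted over the list alone (median 0.68, camera adjusted p = 0.00243). The erythroid markers gave adjusted p = 0.517 with an estimated correlation, and 3.8e-08 to 0.517 over all alternatives (medians of 0.20 to 0.87). Erythroid markers had a median of 0.37 without control 1. Of 39 oxidative phosphorylation genes, the subunits of the respiratory chain, none passed over all genes and 2 were lower adjusted over the list alone (median -0.14, camera adjusted p = 0.0499). The respiratory chain genes gave adjusted p = 0.835 with an estimated correlation, and 0.00496 to 0.835 over all alternatives (medians of -0.23 to -0.01), with a rise to as much as 0.326 without control 1, 6 h array 1 or 3 or any single 12 h array. Respiratory chain genes had a median of -0.04 without 6 h array 1, -0.23 without 6 h array 4 and -0.08 without control 1. Cox5b had -0.45 ± 0.11 (adjusted p = 0.0866). Single members rose or fell in lists that did not pass. Socs3, the feedback inhibitor of cytokine signalling, was the 1 of 20 acute phase genes that rose, at 3.09 ± 0.23 (adjusted p = 1.3e-05). S100a8, a neutrophil calcium-binding protein gene, was the 1 of 7 neutrophil genes that rose, at 2.01 ± 0.41 (adjusted p = 0.0409, up to 0.161 without any single control, 6 h array 2, 3 or 4 or 12 h array 2, 3 or 4, and 0.0169 to 0.161 over all alternatives). The interferon regulator Irf1 was the 1 of 14 interferon targets that fell, at -0.79 ± 0.14 (adjusted p = 0.0178, up to 0.0995 without control 2 or 3, and 0.00380 to 0.229 over all alternatives), and its 3 other probes gave -0.31 to -0.46.

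For all 141 genes called at 6 h the 4 treated arrays lay on one side of the 3 controls, as they did for 13.9% of all genes, against 5.71% by chance. The count of 141 became 71, 70 and 68 without control 1, 2 or 3, 92 without 6 h array 1, 84 without 6 h array 3, and 93 and 91 without 12 h array 2 or 4. It was 58 with only the compared groups, 271 without background correction, 242 with a trended and robust variance and 512 with array brightness as a covariate, and median centring gave 236. Median centring took the median log2 fold change of all genes from -0.02 to 0.12 and the share of calls that were higher from 64.5% to 92.4%. That share was 78.9%, 81.4% and 89.7% without control 1, 2 or 3, and 75% and 76.2% without 6 h array 1 or 3. It was 86.2% with only the compared groups, 76.8% with the replicate block and 86.9% with chip as a block. Under the remaining alternatives it ran from 57.4% to 73.6%.

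The arrays lay on 5 chips, and 3 chips held both controls and 6 h arrays. With chip as a block 61 genes were called at 6 h, 59 of them among the 141, and 18 of the 29 named calls at 6 h stayed. Fos gave 6.76, Atf3 4.47, Egr1 4.16 and Per1 2.43 with this block. All 29 kept their sign. A random block for chip, chosen only after the result was seen, gave 203 genes and all 29 named calls stayed. With the fixed block the calls that ended, at adjusted p of 0.0532 to 0.134, were Habp4 at -1.33 ± 0.27, Tssc8 at -1.0 ± 0.23, Zfp385 at -1.13 ± 0.19, Map3k7ip1 at -0.89 ± 0.17, Zbtb7 at -0.87 ± 0.18 and Gm129 at 1.49 ± 0.31. The others were Cebpb at 0.74 ± 0.15, Cxcl10 at 0.90 ± 0.16, Trp53inp1 at 1.92 ± 0.37, S100a8 at 1.98 ± 0.41 and Irf1 at -0.79 ± 0.15. The block left 4 residual degrees of freedom in place of 8. Within the 3 chips in turn the immediate early genes had medians of 2.03, 2.66 and 2.15, and 2.35 with the block. The glucocorticoid targets had 0.64, 0.83 and 0.65 (0.71 with the block), and the clock genes 0.39, 0.64 and 0.27 (0.32). The integrated stress response had 0.45, 0.19 and 0.41 (0.02), and the p53 targets 0.31, 0.14 and 0.12 (0.19). The inflammatory genes had -0.01, 0.12 and 0.68 (0.19), and the erythroid genes 0.55, -0.07 and 1.39 (0.66). Gluconeogenesis had 0.09, 0.45 and 0.23 and oxidative phosphorylation -0.07, -0.23 and -0.08. With the block both these lists no longer passed, at medians of 0.08 (adjusted p = 0.0553) and -0.07 (adjusted p = 0.0832).

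The second comparison asks how liver transcripts differed from control 12 h after 5'-AMP. Immediate early genes were again the most raised. Atf3 was at least 52.1-fold higher (adjusted p = 4.1e-11), Fos rose by 5.86 ± 0.22 (adjusted p = 1.5e-08), and Egr1 by 4.62 ± 0.44 (adjusted p = 6.1e-05). Nr1d1, the haem-binding repressor of the clock, rose by 4.25 ± 0.36 (adjusted p = 1.8e-05), and Gm129 was at least 12.8-fold higher (adjusted p = 3.6e-06). At 12 h 404 of the 12512 genes passed, 229 higher and 175 lower, with 153 at least 2-fold higher and 50 at least 2-fold lower.

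The remaining genes among the 8 largest increases at 12 h were Fosb, Junb, Gdf15 and Axud1 (now Csrnp1). Fosb was at least 23.6-fold higher by the probe used (adjusted p = 1.5e-08, and 2.0e-10 to 0.886 over all alternatives), against 0.14 (adjusted p = 0.904) by its other probe. Junb rose by 4.59 ± 0.26, Gdf15 by 4.42 ± 0.29 and Axud1 by 4.36 ± 0.18, with adjusted p of 8.9e-07, 2.5e-06 and 3.2e-08. The largest decreases were Oraov1 at -2.66 ± 0.31 (adjusted p = 0.000320) and Ocil (now Clec2d), a ligand of a natural killer cell receptor, at -2.59 ± 0.15 (adjusted p = 9.9e-07). Sertad3 changed by -1.91 ± 0.21 (adjusted p = 0.000213), and Tssc8 was at least 2.3-fold lower, below background on every 12 h array (adjusted p = 0.000821). Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, changed by -1.51 ± 0.18 (adjusted p = 0.000319) and Snx11 by -1.34 ± 0.18 (adjusted p = 0.000953). Il16, a lymphocyte chemoattractant gene, was at least 1.93-fold lower, with a fitted -1.29 ± 0.28 (adjusted p = 0.0278, up to 0.10 without any single control or any single 12 h array, and 0.000506 to 0.248 over all alternatives). The inhibin subunit gene Inhbe changed by -1.29 ± 0.28 (adjusted p = 0.0254, up to 0.112 without control 1 or 3 or 12 h array 1 or 4, and 0.010 to 0.223 over all alternatives).

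At 12 h 16 of the 41 lists passed the camera test, 10 upward and 6 downward. Of 20 immediate early genes 17 rose and none fell, or 19 adjusted over the list alone (median 2.81, camera adjusted p = 5.3e-42). The immediate early genes gave adjusted p = 0.000183 with an estimated correlation, and 3.4e-54 to 0.000183 over all alternatives (medians of 2.18 to 2.96). Of 12 glucocorticoid targets 7 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 1.86, camera adjusted p = 7.2e-12). The glucocorticoid targets gave adjusted p = 0.00792 with an estimated correlation, and 2.1e-15 to 0.00792 over all alternatives (medians of 1.36 to 1.98). Dusp1 rose by 3.04 ± 0.22, Per1 by 2.75 ± 0.24 and Igfbp1, a hepatic binding protein for insulin-like growth factors, by 2.51 ± 0.43 (adjusted p = 0.00613). Of 15 clock genes 6 rose and none fell, with 9 higher and 2 lower adjusted over the list alone (median 0.56, camera adjusted p = 2.3e-09). The clock genes gave adjusted p = 0.0281 with an estimated correlation, and 8.0e-13 to 0.0281 over all alternatives (medians of 0.41 to 0.88). Per2 gave 2.0 ± 0.50 (adjusted p = 0.0516), Arntl 0.36 ± 0.24 (adjusted p = 0.462) and Dbp -0.16 ± 0.27 (adjusted p = 0.813), none past the threshold. Of 15 gluconeogenesis genes 6 rose, or 7 adjusted over the list alone (median 0.35, camera adjusted p = 2.4e-06). The gluconeogenesis genes gave adjusted p = 0.0262 with an estimated correlation, and 1.1e-08 to 0.0262 over all alternatives (medians of 0.23 to 0.62). Gluconeogenesis genes had a median of 0.23 without control 1. Snf1lk rose by 3.44 ± 0.28 (adjusted p = 1.5e-05) and the insulin receptor substrate gene Irs2 by 1.56 ± 0.29 (adjusted p = 0.00927, up to 0.0531 without control 1, and 0.000511 to 0.192 over all alternatives). The gluconeogenic enzyme genes Pck1 and G6pc rose by 1.38 ± 0.31 (adjusted p = 0.0306, up to 0.132 without control 1 or 3 or 12 h array 1, 2 or 4, and 0.00689 to 0.231 over all alternatives) and 0.62 ± 0.14 (adjusted p = 0.0256, up to 0.108 without any single control or 12 h array 1, 2 or 4, and 0.00409 to 0.164 over all alternatives), and the other probe of Pck1 gave 1.24 (adjusted p = 0.109).

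**Figure D3:**
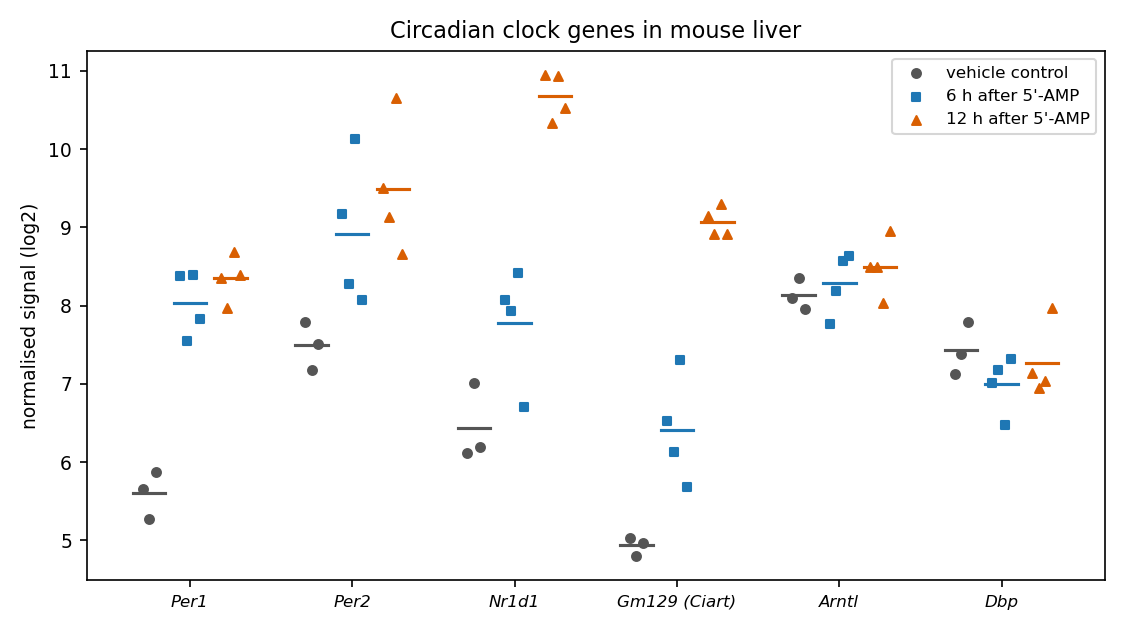
Normalised log2 signal of 6 circadian clock genes on each array (points, 1 animal each; lines, group means; 3 controls, 4 arrays at 6 h and 4 at 12 h). Nr1d1 and Gm129 (Ciart) stand highest at 12 h, and Arntl and Dbp differed from control by 0.36 and -0.16 at 12 h, neither past the threshold.

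At 12 h, of 15 integrated stress response genes 5 rose, and 5 adjusted over the list alone (median 0.12, camera adjusted p = 6.3e-05). The stress response genes gave adjusted p = 0.0262 with an estimated correlation, and 1.9e-06 to 0.0262 over all alternatives (medians of 0.05 to 0.35). Stress response genes had a median of 0.21 without 12 h array 2, 0.07 without 12 h array 4, 0.25 without control 2 and 0.08 without control 3. Beside Atf3 and Gdf15, Ddit4, an inhibitor of mTOR signalling, rose by 2.34 ± 0.21 (adjusted p = 4.1e-05). Of 15 p53 targets 4 rose, and 4 adjusted over the list alone (median 0.11, camera adjusted p = 0.000259). With genes below background at their bounds, and those without a bound left out, the median was 0.19. The p53 targets gave adjusted p = 0.0262 with an estimated correlation, and 1.0e-07 to 0.0262 over all alternatives (medians of 0.03 to 0.34). p53 targets had a median of 0.22 without 12 h array 1, 0.27 without 12 h array 2, 0.06 without 12 h array 3, 0.05 without 12 h array 4, 0.19 without control 2 and 0.26 without control 3. Gadd45a rose by 3.50 ± 0.23, Trp53inp1 by 2.26 ± 0.35 (adjusted p = 0.00291, and 2.6e-05 to 0.102 over all alternatives) and the cell cycle inhibitor gene Cdkn1a by 1.99 ± 0.23, with adjusted p of 2.6e-06 for Gadd45a and 0.000284 for Cdkn1a. Of 11 inflammatory genes 5 rose, or 6 adjusted over the list alone (median 0.59, camera adjusted p = 7.2e-05). With genes below background at their bounds, and those without a bound left out, the median was 0.39. The inflammatory genes gave adjusted p = 0.199 with an estimated correlation, and 5.2e-06 to 0.199 over all alternatives (medians of 0.06 to 0.63). Inflammatory genes had a median of 0.38 without 12 h array 4 and 0.38 without 6 h array 4. Cxcl1 rose by 2.60 ± 0.33 (adjusted p = 0.000646). The chemokine gene Cxcl2, below background on every control array by both its probes, was at least 3.65-fold higher (adjusted p = 7.5e-05). The chemokine gene Ccl4 rose by 1.08 ± 0.26 (adjusted p = 0.0442, up to 0.171 without any single control, 6 h array 2 or any single 12 h array, and 0.00325 to 0.245 over all alternatives).

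The other lists of 12 h had no called member or 1. Fatty acid oxidation and ketogenesis had 0 of 20 genes called and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.00777), and Pdk4, which restrains pyruvate oxidation, gave 0.95 ± 0.30 (adjusted p = 0.118). The fatty acid oxidation genes gave adjusted p = 0.439 with an estimated correlation, and 0.000342 to 0.439 over all alternatives (medians of 0.07 to 0.30), with a rise to as much as 0.203 without control 3. Fatty acid oxidation genes had a median of 0.11 without 12 h array 4. Periportal hepatocyte markers had 1 of 10 called (Pck1) and 2 adjusted over the list alone (median 0.19, camera adjusted p = 0.00551). The periportal markers gave adjusted p = 0.210 with an estimated correlation, and 0.000537 to 0.210 over all alternatives (medians of 0.09 to 0.23). Erythroid markers had 0 of 7 called and 2 adjusted over the list alone (median 0.36, camera adjusted p = 0.0180), with Fech at 0.52 ± 0.13 (adjusted p = 0.0599). The erythroid markers gave adjusted p = 0.439 with an estimated correlation, and 0.000155 to 0.439 over all alternatives (medians of 0.01 to 0.60), with a rise to as much as 0.202 without control 1. Erythroid markers had a median of 0.23 without 12 h array 4, 0.01 without control 1 and 0.60 without control 2. Macrophage and Kupffer cell markers had 0 of 11 called and 1 lower adjusted over the list alone (median -0.66, camera adjusted p = 0.000395), with the complement gene C1qa at -0.98 ± 0.25 (adjusted p = 0.0540). The macrophage markers gave adjusted p = 0.424 with an estimated correlation, and 1.2e-05 to 0.424 over all alternatives (medians of -0.79 to -0.44). Lymphocyte markers had 0 of 6 called and 5 lower adjusted over the list alone (median -0.61, camera adjusted p = 0.00178), with the B cell receptor gene Cd79b at -0.74 ± 0.19 (adjusted p = 0.0553). The lymphocyte markers gave adjusted p = 0.319 with an estimated correlation, and 0.000146 to 0.319 over all alternatives (medians of -1.02 to -0.13). Stellate cell markers had 1 of 8 lower over all genes and 1 adjusted over the list alone (median -0.34, camera adjusted p = 0.0256). The stellate cell markers gave adjusted p = 0.319 with an estimated correlation, and 0.0112 to 0.319 over all alternatives (medians of -0.41 to -0.19). The called marker was Lrat, which stores vitamin A, at -1.07 ± 0.24 (adjusted p = 0.0309, up to 0.151 without any single control or 12 h array 1 or 4, and 0.0125 to 0.151 over all alternatives). Interferon targets had 1 of 14 lower and 2 adjusted over the list alone (median -0.30, camera adjusted p = 0.00421), with Irf1 at -1.20 ± 0.14 (adjusted p = 0.000303) and 2 of its 3 other probes at -0.79 (adjusted p = 0.0954) and -0.50 (adjusted p = 0.380). The interferon targets gave adjusted p = 0.326 with an estimated correlation, and 0.000174 to 0.326 over all alternatives (medians of -0.43 to -0.21). Ribosomal proteins had 0 of 32 called and 0 adjusted over the list alone (median -0.19, camera adjusted p = 0.00178), with Rpl28 at -0.52 ± 0.14 (adjusted p = 0.0690). The ribosomal protein genes gave adjusted p = 0.441 with an estimated correlation, and 4.3e-06 to 0.441 over all alternatives (medians of -0.32 to -0.15). Oxidative phosphorylation had 0 of 39 called and 0 adjusted over the list alone (median -0.19, camera adjusted p = 0.0189), with Ndufs7 at -0.48 ± 0.14 (adjusted p = 0.0980). The respiratory chain genes gave adjusted p = 0.563 with an estimated correlation, and 0.000174 to 0.563 over all alternatives (medians of -0.30 to -0.10), with a rise to as much as 0.155 without control 1 or 12 h array 3. Respiratory chain genes had a median of -0.12 without control 1.

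Further genes passed at 12 h in lists that did not. Socs3 rose by 3.52 ± 0.23 (adjusted p = 2.5e-06) and the angiogenic factor gene Vegfa by 0.90 ± 0.22 (adjusted p = 0.0496, up to 0.207 without any single control, 6 h array 2 or any single 12 h array, and 0.00214 to 0.207 over all alternatives). Herpud1, of the degradation of endoplasmic reticulum proteins, rose by 0.77 ± 0.16 (adjusted p = 0.0224, up to 0.120 without control 2 or 3 or 12 h array 2 or 3, and 0.00561 to 0.268 over all alternatives). The lysosomal protease gene Ctsl rose by 0.97 ± 0.18 (adjusted p = 0.00930, and 0.00196 to 0.114 over all alternatives), and S100a8 by 1.70 ± 0.41 (adjusted p = 0.0445, up to 0.151 without any single control or 12 h array 2, 3 or 4, and 0.0178 to 0.151 over all alternatives). Cirbp, the cold-inducible RNA-binding protein gene, rose by 0.73 ± 0.14 (adjusted p = 0.0131, up to 0.0742 without control 1 or 2, and 0.00239 to 0.199 over all alternatives).

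**Figure D4:**
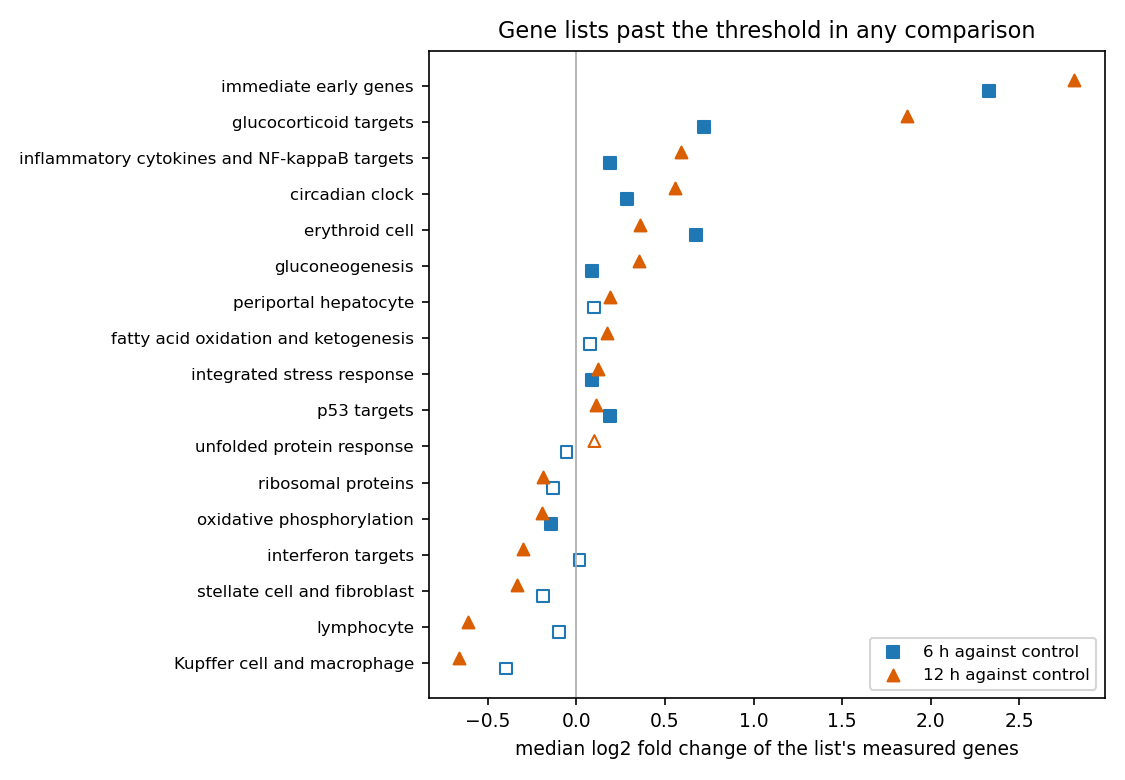
Median log2 fold change of the measured genes of each of the 17 lists past the camera threshold in any of the 3 comparisons, at 6 h (squares) and 12 h (triangles) against control; filled symbols passed in that comparison. The immediate early genes have the highest medians, 2.33 at 6 h and 2.81 at 12 h.

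For 403 of the 404 genes called at 12 h the treated arrays lay on one side of the controls, as for 20.7% of all genes, against 5.71% by chance. The count of 404 became 238, 266 and 220 without control 1, 2 or 3, and 265 and 268 without 12 h array 1 or 4. It was 699 with only the compared groups and 743 with array weights. Median centring took the median log2 fold change of all genes from -0.04 to -0.11 and the share of calls that were higher from 56.7% to 60.3%. That share was 72.7% with chip as a block and 51.1% to 65.9% under the remaining alternatives.

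With chip as a block 132 genes were called at 12 h, 128 of them among the 404, and 26 of the 41 named calls stayed. Atf3 gave 6.21, Fos 5.66, Egr1 4.55 and Nr1d1 4.02 with this block. All 41 kept their sign. The random block gave 464 genes and all 41 named calls stayed. Among the calls that ended with the fixed block, at adjusted p of 0.0565 to 0.268, were Il16 at -1.20 ± 0.37, Inhbe at -1.08 ± 0.32, Herpud1 at 0.68 ± 0.22, Irs2 at 1.31 ± 0.36, Ccl4 at 1.10 ± 0.34, Vegfa at 0.72 ± 0.17 and Trp53inp1 at 2.09 ± 0.46. Others were Ctsl at 1.10 ± 0.25, Pck1 at 1.37 ± 0.41, S100a8 at 2.04 ± 0.51, Lrat at -1.38 ± 0.26, Cirbp at 0.72 ± 0.20 and G6pc at 0.62 ± 0.16. Arrays 1 and 3 of the 12 h group each lay alone on a chip, so the fixed block gave them no weight. Only 2 chips held controls and 12 h arrays. Within them the immediate early genes had medians of 2.71 and 3.31 (2.95 with the block), the glucocorticoid targets 2.11 and 1.97 (1.96) and the clock genes 0.28 and 0.87 (0.62). Gluconeogenesis had 0.32 and 0.69 (0.53), the integrated stress response -0.03 and 0.18 (0.07) and the p53 targets 0.38 and 0.43 (0.20). The inflammatory genes had 0.52 and 0.84 (0.49), fatty acid oxidation 0.09 and 0.35 (0.30) and the periportal markers 0.16 and 0.15 (0.10). Erythroid markers had 0.06 and 0.93 (0.59), macrophage markers -0.46 and -0.42 (-0.51) and lymphocyte markers -0.54 and -0.59 (-0.62). Stellate cell markers had -0.35 and -0.28 (-0.33), and interferon targets -0.01 and -0.44 (-0.31). Ribosomal proteins had -0.17 and -0.18 (-0.17) and oxidative phosphorylation -0.16 and -0.20 (-0.16).

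The third comparison, 12 h against 6 h, tests whether the 2 treated groups differed; whether they differed only in time is not stated. Nr1d1 was higher at 12 h than at 6 h by 2.91 ± 0.33 (adjusted p = 0.00154, and 0.000115 to 0.0988 over all alternatives), and Gadd45b, a stress-induced growth arrest gene, by 2.55 ± 0.21 (adjusted p = 0.000123). Cxcl2 was at least 3.75-fold higher at 12 h, having been below background on every 6 h array by the probe used (adjusted p = 0.000626). Ocil was lower at 12 h, at -2.59 ± 0.14 (adjusted p = 3.7e-06), as were Sertad3 at -1.64 ± 0.19 (adjusted p = 0.00223, and 0.000163 to 0.0924 over all alternatives) and Ppp1r3c at -1.09 ± 0.16 (adjusted p = 0.00867, and 0.00170 to 0.104 over all alternatives). In all 153 genes differed, 71 higher and 82 lower at 12 h.

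The rest of the 5 largest increases were a gene the file names Per, a name without a current match, at 2.06 ± 0.22 (adjusted p = 0.00109, and 0.000167 to 0.0604 over all alternatives), and the sweet taste receptor gene Tas1r2 at 1.84 ± 0.24 (adjusted p = 0.00409, and 0.000312 to 0.177 over all alternatives). On the 6 h arrays other than array 3, Tas1r2 was at 4.75 to 4.83, under the lowest detected signal of 5.31. Its fold is thus largely against background, and ran from 0.83 to 2.17 over all alternatives. The rest of the 5 largest decreases were the early gene Ier2 at -1.26 ± 0.23 (adjusted p = 0.0219, up to 0.0877 without 6 h array 1 or 12 h array 2 or 4, and 0.00113 to 0.160 over all alternatives) and Zfp87 at -1.14 ± 0.17 (adjusted p = 0.00867, and 0.00334 to 0.163 over all alternatives). Cirbp was higher at 12 h by 0.78 ± 0.13 (adjusted p = 0.0141, up to 0.0588 without 12 h array 1 or 4, and 0.00677 to 0.305 over all alternatives). Rbm3, a further cold-induced RNA-binding protein gene, passed in no comparison, with 0.35 ± 0.17 at 6 h and 0.43 ± 0.17 at 12 h.

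By list, 8 of 41 differed between the times, 6 upward and 2 downward, and none of these calls held with an estimated correlation. Of 15 clock genes 3 were higher, or 5 adjusted over the list alone (median 0.31, camera adjusted p = 3.8e-05). The clock genes gave adjusted p = 0.147 with an estimated correlation, and 7.4e-07 to 0.147 over all alternatives (medians of 0.06 to 0.44). Clock genes had a median of 0.19 without 6 h array 2. Of 20 immediate early genes 6 were higher and 1 lower, or 8 and 2 adjusted over the list alone (median 0.42, camera adjusted p = 3.8e-05). The immediate early genes gave adjusted p = 0.137 with an estimated correlation, and 3.4e-08 to 0.137 over all alternatives (medians of 0.20 to 0.52). Of 15 gluconeogenesis genes 0 were called and 4 were higher adjusted over the list alone (median 0.31, camera adjusted p = 0.000356). The gluconeogenesis genes gave adjusted p = 0.137 with an estimated correlation, and 9.6e-06 to 0.137 over all alternatives (medians of 0.04 to 0.32). Gluconeogenesis genes had a median of 0.20 without 12 h array 4, 0.17 without 6 h array 1 and 0.19 without 6 h array 3. Of 12 glucocorticoid targets 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.000667). The glucocorticoid targets gave adjusted p = 0.137 with an estimated correlation, and 2.8e-06 to 0.137 over all alternatives (medians of 0.16 to 0.49). Of 15 integrated stress response genes 4 were higher, or 6 higher and 1 lower adjusted over the list alone (median 0.12, camera adjusted p = 0.00256); with median centring the median was -0.12, against -0.21 for all genes, and the call stayed. The stress response genes gave adjusted p = 0.137 with an estimated correlation, and 0.000140 to 0.137 over all alternatives (medians of -0.12 to 0.26). Stress response genes had a median of 0.03 without 12 h array 1. Of 13 unfolded protein response genes, which encode chaperones of the endoplasmic reticulum, 0 were called and 0 adjusted over the list alone (median 0.29, camera adjusted p = 0.0143). The unfolded protein genes gave adjusted p = 0.664 with an estimated correlation, and 0.00105 to 0.998 over all alternatives (medians of -0.07 to 0.40), with a rise to as much as 0.156 without 6 h array 2 or 4 or 12 h array 3. Unfolded protein genes had a median of 0.13 without 12 h array 3 and 0.16 without 6 h array 4. Of 14 interferon targets 0 were called and 4 were lower adjusted over the list alone (median -0.30, camera adjusted p = 0.000356). The interferon targets gave adjusted p = 0.352 with an estimated correlation, and 1.4e-05 to 0.352 over all alternatives (medians of -0.54 to -0.19). Of 6 lymphocyte markers 0 were called and 1 was lower adjusted over the list alone (median -0.48, camera adjusted p = 0.0143). Their median was -0.37 with genes below background at their bounds and those without a bound left out. The lymphocyte markers gave adjusted p = 0.629 with an estimated correlation, and 0.000696 to 0.952 over all alternatives (medians of -0.58 to -0.08), with a rise to as much as 0.193 without 6 h array 4. Lymphocyte markers had a median of -0.32 without 6 h array 4.

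The count of 153 became 64 without 6 h array 2, and 70, 88 and 56 without 12 h array 1, 2 or 4. It was 96 with only the compared groups, 282 without background correction, 251 with a trended and robust variance and 851 with median centring, which took the median of all genes from -0.01 to -0.21 and the share of calls that were higher from 46.4% to 8.11%. Against that -0.21 of all genes, the list medians with median centring were 0.06 for the clock, 0.27 for immediate early genes, 0.04 for gluconeogenesis, 0.16 for glucocorticoid targets and 0.08 for the unfolded protein response. Interferon targets had -0.54 and lymphocyte markers -0.58, and only the lymphocyte markers were no longer called. The share of calls that were higher rose to 59.4% with only the compared groups, 62.4% with the replicate block and 80% with chip as a block. It was 60.8% without 6 h array 1 and 61.4%, 62.5% and 60.7% without 12 h array 1, 2 or 4. Under the remaining alternatives this share ran from 36.8% to 56.3%. For all 153 genes the arrays of both times lay apart, as for 9.81% of all genes, against 2.86% by chance.

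With chip as a block 5 genes differed between the times, all 5 among the 153. The random block, chosen only after the result was seen, gave 174 genes, 152 of them among the 153, and all 11 named calls stayed. The values that follow are from the fixed block, which gave no weight to 12 h arrays 1 and 3, each alone on a chip. Atf3, with 1.75 (adjusted p = 0.0382, and 1.0e-06 to 0.0382 over all alternatives), and LOC229599, with 2.20 (adjusted p = 0.0382, and 1.9e-05 to 0.0382 over all alternatives), were named after their values were seen. Of the 11 named calls 3 stayed, Cxcl2 (adjusted p = 0.0158, 0.000108 to 0.0158 over all alternatives), Gadd45b (adjusted p = 0.0382, 7.6e-06 to 0.0382 over all alternatives) and Ocil (adjusted p = 0.00919, 2.5e-08 to 0.00919 over all alternatives). The other 8 ended at adjusted p of 0.0604 to 0.305, each keeping its sign, with Nr1d1 at 2.70 ± 0.39, Per at 2.04 ± 0.26, Tas1r2 at 1.46 ± 0.28, Sertad3 at -1.71 ± 0.24, Ier2 at -1.59 ± 0.28, Zfp87 at -1.29 ± 0.23, Ppp1r3c at -1.26 ± 0.19 and Cirbp at 0.79 ± 0.20. Within the 2 chips that held both times the clock genes had medians of -0.08 and 0.59 (0.19 with the block) and the immediate early genes 0.34 and 0.27 (0.31). Gluconeogenesis had 0.19 and 0.34 (0.29), the glucocorticoid targets 0.43 and 0.69 (0.48) and the integrated stress response 0.37 and 0.30 (0.17). Interferon targets had -0.23 and -0.44 (-0.34), lymphocyte markers 0.13 and -1.18 (-0.50) and the unfolded protein response -0.04 and 0.22. With the block the unfolded protein response turned to -0.07 (adjusted p = 0.998).

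Many genes called at 6 h were called again at 12 h. Of the 141 genes 98 passed at both times in the same direction, 75 higher and 23 lower, and 0 in opposite directions. Independent lists of these sizes would share 1.67 and 0.699, and 100 simulated sets of unchanged groups against shared controls gave a mean of 0.01 each. With no change simulated almost no gene was called, so that 0.01 is no reference for the overlap. Across genes, which are not independent replicates, the log2 fold changes of both times correlated at r = 0.735, against 0.572 simulated, with a covariance of 0.103 against 0.0232 (95% of simulations 0.0219 to 0.0247). Both comparisons use the same 3 controls, too few to split, so part of the overlap in genes and of r may come from them. The simulated r and covariance already include shared controls. The covariance exceeded the simulated one by 0.0801. The simulated genes varied independently of each other, so the simulated interval is narrower than for genes that vary together. The overlap of 98 became 55, 59 and 54 without control 1, 2 or 3, 57 with only the compared groups, 44 with chip as a block and 154 with the brightness covariate. Of the 43 genes called only at 6 h and the 98 shared, 6 moved toward control and 16 away from it by the 12 h against 6 h test. Of the 306 genes called at 12 h and not at 6 h, 85 also differed between the times.

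Genes named in advance that passed in neither comparison with control included Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.19 ± 0.29 at 6 h and -0.70 ± 0.29 at 12 h. The hepatokine gene Fgf21 gave -0.01 ± 0.27 and 0.72 ± 0.27, and the coactivator gene Ppargc1a -0.27 ± 0.14 and -0.28 ± 0.14. Among genes of adenosine handling, adenosine kinase (Adk) gave 0.03 ± 0.10 and -0.01 ± 0.10, and the ectonucleotidase gene Nt5e 0.28 ± 0.19 and 0.13 ± 0.19. At 6 h Nr1d1 gave 1.34 ± 0.36, Per2 1.42 ± 0.50, Arntl 0.16 ± 0.24, Dbp -0.44 ± 0.27, Pck1 0.83 ± 0.31, G6pc 0.60 ± 0.14, Pdk4 0.61 ± 0.30 and Cirbp -0.05 ± 0.14, none past the threshold by the probe used. The other probe of Nr1d1 passed at 6 h, with 1.39 (adjusted p = 0.0325). The pancreatic colipase gene Clps gave 0.81 ± 1.03 and 0.16 ± 1.03, and was detected on 1 array of each group. Pnlip and Ada did not pass the filter on dim probes.

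The other 24 lists passed the camera test in no comparison, and their medians are given for 6 h, 12 h and 12 h against 6 h in turn. Heat shock genes had medians of 0.02, 0.00 and 0.04 (adjusted p = 0.808, 0.441 and 0.586), and glycolysis genes had 0.05, 0.06 and 0.02 (adjusted p = 0.915, 0.639 and 0.496). Fatty acid synthesis genes had medians of 0.11, -0.02 and -0.09 (adjusted p = 0.263, 0.790 and 0.318), and cholesterol synthesis genes had -0.02, -0.31 and -0.05 (adjusted p = 0.989, 0.411 and 0.328). Bile acid genes had medians of 0.09, 0.13 and 0.05 (adjusted p = 0.154, 0.148 and 0.958), and acute phase genes had 0.00, -0.05 and 0.04 (adjusted p = 0.603, 0.302 and 0.563). Hypoxia targets had medians of -0.02, 0.06 and 0.09 (adjusted p = 0.638, 0.166 and 0.328), and cell cycle genes had 0.09, -0.07 and -0.12 (adjusted p = 0.209, 0.707 and 0.311). Of the fatty acid synthesis genes the elongase gene Elovl6 was lower at 12 h than at 6 h.

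Tricarboxylic acid cycle genes had medians of 0.15, 0.07 and -0.12 (adjusted p = 0.0518, 0.166 and 0.513), and ribosome biogenesis genes had -0.09, -0.20 and -0.12 (adjusted p = 0.636, 0.0583 and 0.151). Purine and adenosine genes had medians of -0.00, 0.06 and 0.02 (adjusted p = 0.603, 0.168 and 0.550), and antioxidant genes had -0.05, 0.08 and 0.03 (adjusted p = 0.764, 0.379 and 0.214). Xenobiotic metabolism genes had medians of 0.12, 0.12 and 0.04 (adjusted p = 0.260, 0.0761 and 0.556), and amino acid catabolism genes had -0.01, 0.02 and 0.06 (adjusted p = 0.854, 0.246 and 0.311). Proteasome subunits had medians of -0.05, -0.09 and -0.07 (adjusted p = 0.671, 0.148 and 0.311), and autophagy and lysosome genes had 0.05, 0.04 and 0.04 (adjusted p = 0.260, 0.166 and 0.782). Of these lists only autophagy and lysosome held a gene past the threshold by the probe used, Ctsl at 12 h. Other probes of the cycle gene Pdhb passed at 12 h, with 3.14 (adjusted p = 0.0020) and 0.65 (adjusted p = 0.0457). Only the former also passed at 6 h, with 2.23 (adjusted p = 0.0466), and a further probe passed at neither time. By the probe used Pdhb gave 0.25 (adjusted p = 0.393) at 6 h and 0.47 (adjusted p = 0.106) at 12 h.

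Among cell type markers, hepatocyte markers had medians of -0.08, 0.02 and 0.15 (adjusted p = 0.378, 0.691 and 0.136). Pericentral markers had medians of 0.00, 0.05 and -0.01 (adjusted p = 0.764, 0.790 and 0.896), and neutrophil markers had 0.06, -0.11 and -0.17 (adjusted p = 0.407, 0.284 and 0.988). Endothelial markers had medians of 0.11, -0.12 and -0.23 (adjusted p = 0.603, 0.639 and 0.215), and cholangiocyte markers had -0.11, -0.13 and -0.00 (adjusted p = 0.777, 0.854 and 0.903). Pancreatic acinar markers had medians of 0.39, 0.16 and -0.42 (adjusted p = 0.260, 0.677 and 0.320), and adipocyte markers had -0.18, -0.32 and -0.14 (adjusted p = 0.764, 0.707 and 0.988). The skeletal muscle markers had medians of 1.20, 0.08 and -1.0 (adjusted p = 0.237, 0.707 and 0.311). Of these 3 markers, with an estimated correlation of 0.963, Atp2a1 was at 9.86 on 6 h array 2 against 5.0 to 5.14 on the other 6 h arrays. Detected on every control array were all 11 hepatocyte, 10 periportal, 10 pericentral, 11 macrophage, 9 endothelial, 8 stellate and 4 cholangiocyte markers. Of the neutrophil markers 4 of 7 were so detected, of the lymphocyte markers 4 of 6, of the erythroid markers 5 of 7, of the acinar markers 2 of 6, of the adipocyte markers 2 of 2 and of the muscle markers 0 of 3. The median, the mean and the test differed in sign for 7 lists at 6 h, 7 at 12 h and 3 between the times, none of them among the lists that passed. They were at 6 h glycolysis, cholesterol, hypoxia, purine, amino acid, pericentral and adipocyte genes. At 12 h they were fatty acid synthesis, acute phase, cell cycle, pericentral, neutrophil, acinar and adipocyte genes, and between the times bile acid, neutrophil and cholangiocyte genes.

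Lists also passed in comparisons where they had not been called, under some of the 27 alternatives (26 for skeletal muscle), given here with the adjusted p over all alternatives. At 6 h they were macrophage markers in 7 (0.000130 to 0.835), ribosomal protein genes in 6 (0.00481 to 0.835), tricarboxylic acid cycle genes in 6 (0.00143 to 0.240), cell cycle genes in 2 (0.0175 to 0.835) and fatty acid oxidation genes in 1 (0.0333 to 0.963). The others at 6 h were fatty acid synthesis genes in 1 (0.0228 to 0.841), hepatocyte markers in 1 (0.00219 to 0.835), pancreatic acinar markers in 1 (0.0143 to 0.930) and skeletal muscle markers in 1 (0.0159 to 0.835). At 12 h they were ribosome biogenesis genes in 9 (0.00838 to 0.518), xenobiotic metabolism genes in 4 (0.0292 to 0.342), acute phase genes in 2 (0.0162 to 0.789), amino acid catabolism genes in 2 (0.00750 to 0.536) and cholesterol synthesis genes in 2 (0.0118 to 0.966). Further lists at 12 h were neutrophil markers in 2 (0.0480 to 0.741), proteasome subunits in 2 (0.0292 to 0.525), tricarboxylic acid cycle genes in 2 (0.00269 to 0.704) and unfolded protein genes in 2 (0.0195 to 0.786). Between the times they were hepatocyte markers in 4 (0.00122 to 0.664), p53 targets in 4 (0.00277 to 0.352), ribosome biogenesis genes in 4 (0.0202 to 0.703), stellate cell markers in 4 (0.0156 to 0.566) and cholesterol synthesis genes in 3 (0.00652 to 0.843). A further 5 were macrophage markers in 3 (0.00108 to 0.956), fatty acid oxidation genes in 2 (0.0320 to 0.703), periportal markers in 2 (0.0272 to 0.664), ribosomal protein genes in 2 (0.0135 to 0.872) and cell cycle genes in 1 (0.0348 to 0.958). The last were endothelial markers in 1 (0.0419 to 0.703), fatty acid synthesis genes in 1 (0.00423 to 0.765), inflammatory genes in 1 (0.0304 to 0.709), antioxidant genes in 1 (0.00652 to 0.703) and skeletal muscle markers in 1 (0.0142 to 0.997). With chip as a block the lists of these that passed at 12 h included cholesterol synthesis (median -0.42, adjusted p = 0.0118), acute phase (median 0.12, adjusted p = 0.0162), ribosome biogenesis (median -0.27, adjusted p = 0.0118) and neutrophil genes (median 0.72, adjusted p = 0.0485). The medians of the acute phase and neutrophil genes were of the other sign without the block. Between the times fatty acid synthesis (median -0.32, adjusted p = 0.00423), cholesterol synthesis (median -0.17, adjusted p = 0.0129) and ribosome biogenesis (median -0.19, adjusted p = 0.0251) were among those that passed with this block.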

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

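The splits of the arrays were planned. The test for pancreatic tissue was planned too, though its array was picked by its high Clps value. The tests of Clps induction, the first principal component (both) and time of day were chosen only after the result was seen.

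Single arrays lay far from the others of their group in 12 of 226 groups of 4 arrays examined, and chance flags about 1 in 20 groups. At 6 h, Atf3 was at 9.52 on array 3 against 9.20 to 9.24 on the others, and Tas1r2 at 5.69 on array 3 against 4.75 to 4.83. On 6 h array 2, Atp2a1, a muscle calcium pump gene, was at 9.86 against 5.0 to 5.14, Cxcl10 at 6.19 against 6.64 to 6.74, Egr1 at 13.48 against 13.75 to 13.77 and Irf1 at 10.64 against 10.99 to 11.01. Per was at 5.42 on 6 h array 4 against 6.34 to 6.5 on the others. At 12 h, Ftl1 was at 14.61 on array 4 against 14.26 to 14.30. Npm1 was at 11.87 on array 2 against 11.60 to 11.64, and Rpl28 at 13.16 against 13.33 to 13.36.

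Clps, the pancreatic colipase gene, was at 9.30 on 6 h array 4 against 4.60 to 4.79 on the others of its group, and at 7.02 on 12 h array 2 against 4.45 to 4.68. Only 2 of the 8 treated arrays lay above every control, so induction by 5'-AMP in most animals was not seen. This count restates the pattern that flagged Clps and tests nothing further. Pancreatic tissue in the liver piece of 6 h array 4 is a candidate explanation: the median of the 5 other measured acinar markers was 2.14 above that on the other 10 arrays. On 6 h array 4 that median was the value of Reg1, 8.21, and Reg1 was at 9.21 on control 2 (named after its values were seen). Marker by marker the median difference was 0.752 with 2 of 5 above 1, against 4.65 for Clps, and 2 of the 6 acinar markers (Amy2 and Ela1, named after their values were seen) were detected on all arrays. Without the filter 11 of 18 other acinar genes lay more than 1 above on that array (median 1.73), and 9 of 18 on 12 h array 2 (median 0.85). Pnlip, the pancreatic lipase gene named in advance, was among them. It was at 9.30 on 6 h array 4 and 6.98 on 12 h array 2, against 4.42 to 4.69 on the other arrays.

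The 12 h and 6 h groups, which may differ in more than time, differed by the 12 h against 6 h test for 17 of the 108 genes named in the comparisons with control. Higher at 12 h were Nr1d1 (2.91), Gm129 (2.66), Cxcl2 (2.36), Atf3 (1.79), Gadd45a (1.63), Ddit4 (1.43), Axud1 (1.41), Fosb (1.31, by the probe used), Cdkn1a (1.16), Habp4 (0.98), Cebpb (0.84) and Cirbp (0.78). Lower were Ocil (-2.59), Sertad3 (-1.64), Ppp1r3c (-1.09), Elovl6 (-0.98) and Reln (-0.62). By other probes Habp4 gave 0.17 (adjusted p = 0.734), Cdkn1a 0.98 (adjusted p = 0.117) and 1.02 (adjusted p = 0.116), and Fosb 0.27 (adjusted p = 0.80) (0.00163 to 0.756 over all alternatives).

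All 17 of these genes still passed with chip as a random block (adjusted p of 0.0459 or less). With chip as a fixed block 3 of them did (Atf3, Cxcl2 and Ocil), and 14 did not, at adjusted p of 0.0924 to 0.383. All 17 kept their sign. The fixed block gave no weight to 12 h arrays 1 and 3, each alone on a chip. The folds of the 14 with the fixed block, which left 4 residual degrees of freedom in place of 8, were Nr1d1 2.70 ± 0.39, Gm129 2.47 ± 0.38, Gadd45a 1.48 ± 0.32, Ddit4 1.64 ± 0.25, Axud1 1.36 ± 0.23, Fosb 1.28 ± 0.26 and Cdkn1a 1.29 ± 0.25. For the others they were Habp4 1.13 ± 0.33, Cebpb 0.97 ± 0.18, Cirbp 0.79 ± 0.20, Sertad3 -1.71 ± 0.24, Ppp1r3c -1.26 ± 0.19, Elovl6 -1.29 ± 0.26 and Reln -0.75 ± 0.16. Leaving out 1 array ended 5 of the 17: Cdkn1a without 6 h array 2 or 12 h array 3 or 4 (0.00720 to 0.191 over all alternatives), Cirbp without 12 h array 1 or 4 (0.00677 to 0.305 over all alternatives), Elovl6 without control 3, any single 6 h array or 12 h array 1, 2 or 4 (0.0103 to 0.203 over all alternatives), Habp4 without control 2 or 3, 6 h array 1, 3 or 4 or any single 12 h array (0.0272 to 0.383 over all alternatives) and Reln without 6 h array 1, 3 or 4 or 12 h array 1, 2 or 4 (0.00680 to 0.246 over all alternatives).

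Of the lists 8 differed too, and none of them passed with an estimated correlation (adjusted p of 0.137 to 0.664). The medians were 0.31 for the clock, 0.29 for the unfolded protein response, 0.12 for the integrated stress response, 0.31 for gluconeogenesis, 0.42 for the immediate early genes, 0.38 for glucocorticoid targets, -0.30 for interferon targets and -0.48 for lymphocyte markers. The unfolded protein response turned to -0.07 with chip as a block.

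Nr1d1 and Gm129 (now Ciart), both clock repressors, were raised at 12 h. A difference in the time of day of death is a candidate explanation, and it cannot be told apart from an effect of 5'-AMP because the clock time of death is not given for any group. Dbp, which swings widely over the day in liver, differed by -0.16 (95% interval -0.74 to 0.42), and Arntl by 0.36 (-0.16 to 0.88). An effect of 5'-AMP on these genes stays open as well.

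The 6 h arrays were spread over 41.9 on the first principal component, against 7.81 at 12 h and 1.56 among the controls. A difference between chips as the whole cause was argued against, since the 6 h arrays that share a chip lay 32.1 apart. Array brightness stays open: the slope on log2 mean signal was -9.70 (95% interval -32.3 to 12.9) in the other groups and -85.2 within the 6 h group, but 6 h arrays had signals up to 635, beyond the highest of the other groups, 542. A biological difference between the animals at 6 h was not tested.

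Chance as the source of the group differences was tested by splitting the arrays of the compared groups in all 35 ways. In each comparison 1 split, the real one, gave as many genes. In fits of the compared groups alone the real split gave 58 genes at 6 h, 699 at 12 h and 96 between the times. The highest other split gave 3, 0 and 1. Each other split mixes the groups, so a real difference widens its spread and lowers its count. A share of 1 in 35 is the smallest this test can give, and it took no account of chips. Chance is therefore argued against but not excluded.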

How the results depend on the processing

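The alternatives chip as a random block, array brightness and lists without shared members were chosen only after the result was seen. Of 81 calls of named genes 42 held under all alternatives that gave them a value, and of 33 list calls 7: immediate early genes at 6 h, and at 12 h clock, glucocorticoid, gluconeogenesis, immediate early, integrated stress response and p53 genes. With the stricter filter only 54 of the 81 had a value. The other calls, among them Fos and Atf3 at both times, were not tested with that filter. With an estimated correlation 7 of 33 list calls held, with fry 21 and with the stricter filter 21. Without members shared with the immediate early genes the integrated stress response at 6 h ended (adjusted p = 0.0917, and 9.0e-05 to 0.126 over all alternatives). Gluconeogenesis and oxidative phosphorylation share 0 members with those genes, so this alternative did not test them: at 6 h their adjusted p moved to 0.0562 only because the p of other lists changed (0.0175 to 0.430 and 0.00496 to 0.835 over all alternatives). With the authors' values gluconeogenesis and oxidative phosphorylation at 6 h ended too.

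The number of genes at 6 h (141) became 271 without background correction, 236 with median centring, 58 with only the compared groups, 242 with a trended and robust variance, 61 with chip as a block and 512 with brightness as a covariate. At 12 h (404) it became 699 with only the compared groups, 743 with array weights and 132 with chip as a block. Between the times (153) it became 282 without background correction, 851 with median centring, 96 with only the compared groups, 251 with a trended and robust variance, 93 with the replicate block and 5 with chip as a block. The overlap (98) became 57, 44 and 154 with only the compared groups, chip as a block and brightness. Leaving out 1 array gave 68 to 208, 220 to 500, 56 to 197 and 54 to 129. Chip as a random block (correlation 0.12 within chips) gave 203, 464, 174 and 115 and kept all 81 calls of named genes; lists were not tested with it. Chip as a fixed block left 4 residual degrees of freedom in place of 8. It also gave no weight to 12 h arrays 1 and 3, each alone on a chip. The 12 h values with this block thus rest on 12 h arrays 2 and 4. Otherwise the cause was not tested.

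Reversed were Fosb at 6 h with the stricter filter (-0.13) and Dido1 at 6 h without control 1, 2 or 3 (0.23, 0.17 and 0.35; -1.07 to 0.35 over all arrays left out), where another probe was taken, and the unfolded protein response between the times with chip as a block (-0.0658). The cause of the last was not tested. Lists were judged by the direction of the test, so the integrated stress response was not counted, though its median turned to -0.12 with median centring between the times and to -0.00 without control 1 at 6 h, with the call kept. A change of sign past the threshold under neither setting was not counted. Among the remaining values of single genes 252 were weaker and 110 stronger, and of lists 91 and 87. The skeletal muscle list gave no value with the stricter filter. Signal over background limits dim genes, whose folds are bounds. Arrays of the same number were not paired (r from -0.183 to 0.445, 4 of 10 above 0.1, 3 of 11 best matched to their own number). The pair at 0.445 shared a chip. Across all pairs of arrays from different groups the mean r was 0.166 on the same chip and -0.0418 on different chips.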

Other observations

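Of the 50 genes lower at 6 h, 32 bore only clone or predicted names (64%, exact Clopper-Pearson 95% interval 49.2% to 77.1%), against 36.3% of all genes tested. This was noticed after the values were seen. The interval treats genes as independent draws, though all were measured on the same arrays, so it does not measure spread between animals. The shares in the other groups were 25.3% of the 91 genes higher at 6 h, 38.4% of the 229 higher and 45.1% of the 175 lower at 12 h, and 28.2% of the 71 higher and 36.6% of the 82 lower at 12 h than at 6 h.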
